A study of Homo sapiens with 6 samples.

How the data were processed

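RNA of peripheral blood mononuclear cells (PBMC) was measured on 6 single-colour oligonucleotide arrays of the Affymetrix HuGeneFL type, on which a gene is read by 1 or more probe sets. All 6 samples carry the title NOR with a number and make 1 group, called NOR 1 to NOR 6 here. The labels do not expand NOR, and their descriptions name pulmonary arterial hypertension for all 6, so whether a sample came from a patient was not settled. No contrast between groups exists among these samples, and other samples were not analysed here. Nothing in the labels says that the samples came from separate donors, so the spread between these 6 samples can be technical.

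The deposited values are linear intensities, 1 per probe set and sample, between 0.7 and 53028.5. Each array had a median intensity of 62.0 over its 7129 probe sets, so the deposited intensities had been brought to a common median. The software, the background correction and the scaling method are not given in the sources used here. A block of 1043 probe sets (14.6%) held exactly 1.0 on all 6 arrays, although 58 single values elsewhere lay below 1, and the 13 other probe sets that held 1.0 did so on at most 2 arrays. These 1043 probe sets were taken as filled in and were left out, a choice made after the values were seen. Arrays give no counts, so their number limits the precision.

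A table of the platform's probe sets gave 1 gene symbol for 5709 probe sets, several for 321 and none for 1099. Probe sets with several genes were left out. Current symbols were taken by gene identifier from a RefSeq gene table, which matched 5704 probe sets, and no coordinates were used. The 6028 measured probe sets that are not controls set the scale: each array was divided by its 75th percentile and multiplied by the mean of the 6 percentiles, which gave factors between 0.917 and 1.14. Scaled intensities were floored at their pooled 40th percentile (58.5), put on the log2 scale and kept when the mean over the 6 samples was at least 2 times the floor (117.1). The brightest probe set stood for its gene. Y-linked genes, XIST and genes whose signal can show a donor's genotype were left out for privacy, 7 genes past the filter in all. This left 2165 genes. The scaled intensities below are linear, and SD values are on the log2 scale over n = 6 samples.

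The variance of each gene was compared with the variance that the intensity trend of limma predicts (squeezeVar with a robust prior, F test of the upper tail, Benjamini-Hochberg over 2165 genes). Gene lists of blood cell types, responses and complexes were written before the data were examined, as were the tests and the rule for naming genes. Lists with at least 5 measured genes were tested, 21 of 24. For each, the mean pairwise Pearson correlation of its genes (one-sided) and their median SD (two-sided) were set against 10000 random gene lists of the same size matched on deciles of expression. The smallest p these can give is 0.0001 one-sided. Fisher's exact test (two-sided) compared each list with the genes past the variance threshold. A list score is the mean log2 deviation of the list's genes from their own means, and the scores of 7 cell type lists were correlated in 21 pairs with exact permutation over 720 orders. Dixon's ratio with the critical value 0.625 marked single samples far from the others. The threshold was an adjusted p under 0.05 throughout.

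Named genes were the 25 with the smallest adjusted p among those past the variance threshold, or all if fewer passed, and for each list its first 4 measured genes in the written order and those with the largest and the smallest SD. The rule also took any gene of a list past Dixon's value where the list's own score passed it. It gave 119 genes, and any other named gene was chosen after its values were seen.

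On simulated data for the 2165 genes, the variance test recovered 2% of genes whose SD was multiplied by 2, 10% by 4, 66% by 8 and 78% by 12, with 0 false calls. On simulated lists, the covariation test recovered 19 of 20 lists that shared a factor and called 1 of 40 others. The test of list SD recovered 20 of 20 lists whose SD was multiplied by 2 and called 1 of 40 others. Apart from the shared factor, simulated genes were independent normal values around the fitted trend, with no floor and no array-wide component. Error rates on the real values may therefore differ.

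Alternatives were other floors, other scalings, no filter or a stricter filter, the mean of a gene's probe sets, other forms of each test and each sample left out in turn. After the values were seen, 3 more were added: a block on the array sets found from the spike-in controls, the filled-in probe sets in the percentiles, and enrichment among genes with an unadjusted p under 0.05. The work used R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.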

Results

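Gene expression was measured by array in 6 PBMC samples, all titled NOR, from a series on pulmonary arterial hypertension. PBMC are the lymphocytes, monocytes and related cells of blood, with platelets and some other cells that stay with them. Between 57.9% and 63.0% of probe sets lay above the floor on each array. Across the 2165 genes, pairs of arrays correlated with a median Pearson r of 0.929 (SD 0.0223 over 15 pairs, range 0.881 to 0.968) and a median Spearman rho of 0.900, where genes are not independent replicates. No pair held identical values. Across all measured probe sets the median Pearson r was 0.966.

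The bacterial transcripts BioC and BioD, which are spike-in controls and not blood RNA, split the arrays into 2 sets. The log2 ratio of the BioD to the BioC 3' probe sets lay between 1.17 and 1.40 in NOR 1, NOR 2 and NOR 5 (array set A) and between 3.50 and 3.63 in NOR 3, NOR 4 and NOR 6 (array set B). The labels give no batch, and the split was found after the values were seen. Pairs within a set correlated with a median r of 0.948 (6 pairs) and pairs across the sets with 0.9175 (9 pairs). The first principal component of the genes tested held 44.6% of their variance. Its scores separated the sets, from -14.3 to -9.81 in set A and from 3.19 to 18.3 in set B. The mean r of each list that passed the covariation test is therefore also given with the set as a block, and with it 0 of the other 12 lists passed (adjusted p from 0.0936 to 0.707).

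The first question was which genes differed between the 6 samples by more than genes of like brightness. MYOM2, which encodes a protein of the muscle sarcomere, ranged from the floor in NOR 6 to an intensity of 3326 in NOR 5, at least 56.8-fold (SD 2.47). LTF, which encodes lactoferrin of neutrophil granules, ranged from 93.7 in NOR 5 to 2404 in NOR 4, 25.7-fold (SD 2.04). CAMP, which encodes the granule peptide cathelicidin, ranged from the floor in NOR 5 to 1787 in NOR 3, at least 30.5-fold (SD 2.03). These 3 genes passed the variance test, each with an adjusted p of 0.026. A typical gene had an SD of 0.33 (median, quartiles 0.24 and 0.45) and a highest sample 1.82-fold above its lowest. The highest sample exceeded the lowest by over 2-fold for 816 genes (37.7%), over 4-fold for 98 and over 10-fold for 12. An unadjusted limma p under 0.05 was reached by 133 genes, where the fitted model gives 108.2. The trend and the prior were fitted to these same variances. A count near 108.2 therefore follows largely from the fit and does not measure how far the samples differ. The 3 calls depended on the samples, the scaling, the filter and the variance model: 0 genes passed without NOR 4, NOR 5 or NOR 6, under quantile normalization, with no scaling, with no filter (adjusted p = 0.740 for the 3), with filled-in probe sets counted (0.0937), without the trend (0.245) or without the robust prior (0.0983), and 15 passed without NOR 1. With the array set as a block 1 gene passed, MYOM2, and with the lower floor LTF did not pass (adjusted p = 0.0642).

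Where a gene had 2 probe sets past the filter, their correlation over the 6 samples had a median of 0.349 (97 genes, quartiles -0.175 and 0.660). It was 0.795 for the 11 such genes with an unadjusted limma p under 0.05 and 0.276 for the other 86. Of the 3 genes past the variance threshold, 0 had a second probe set past the filter, so their calls were not checked in this way.

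Neutrophil genes were the most variable cell type list. The median SD of its 18 measured genes was 1.29, against 0.35 for random lists (adjusted p = 0.0014), and their mean pairwise r was 0.35 (adjusted p = 0.000525). Adjusted over the list alone, 14 of the 18 genes passed the variance test, and 2, LTF and CAMP, did so over all genes tested. Members did not all move alike. LTF stood at 2167 in NOR 3 and 2404 in NOR 4, where FCGR3B, the Fc receptor of mature neutrophils, stood at 322 and 742. In NOR 1 LTF stood at 110.0 and FCGR3B at 3135, and in NOR 6 both were low, at 281.5 and 393. The SD of FCGR3B was 1.32, or 0.57 with the block. The receptor genes CXCR1 (143 to 706, SD 0.85, or 0.52 with the block) and CXCR2 (85.7 to 306, SD 0.67, or 0.37 with the block) were also lowest in array set B, and CSF3R had an SD of 0.34. The list score was 1.27 in NOR 3 and 1.02 in NOR 4 and between -0.93 and -0.23 in the other 4 samples. It was 1.08 higher on the log2 scale in array set B than in set A (exact permutation p = 0.3, two-sided, where 0.1 is the smallest possible). The list score averages members that differed between the sets in opposite directions, so it can hide their relation to the set. The granule protein gene LCN2 differed by 2.13 (set B minus A) and FCGR3B by -2.22. With the set as a block the mean r was 0.56 (adjusted p = 0.000525), and with no scaling it was 0.27 (adjusted p = 0.0638).

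**Figure D1:**
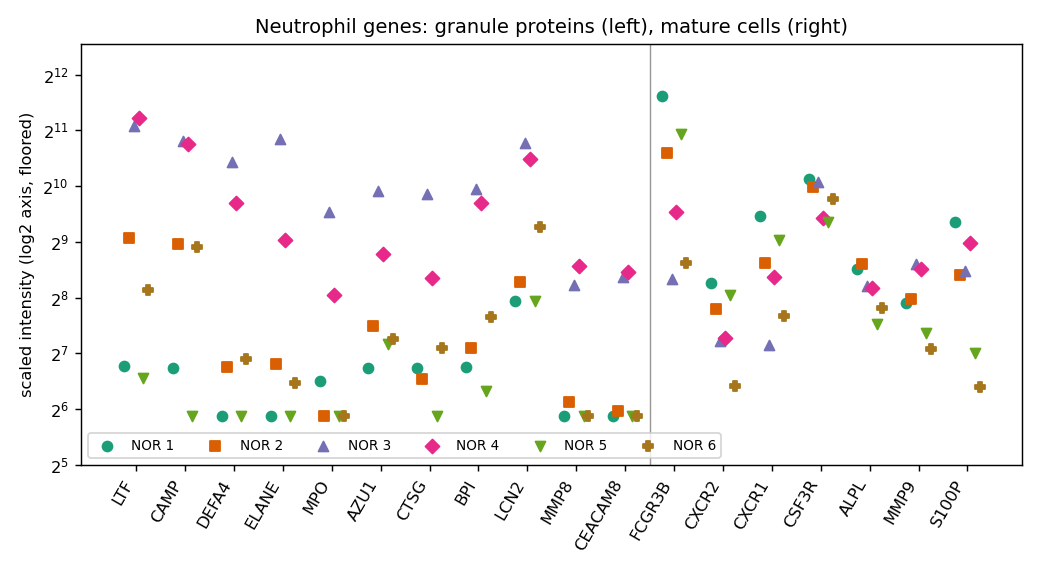
Scaled, floored intensity (log2 axis) of 11 granule protein genes (left of the line) and 7 genes of mature neutrophils (right) in the 6 NOR samples, 1 point per sample. NOR 3 and NOR 4 hold the highest values of LTF and CAMP and lower values of FCGR3B than NOR 1, where FCGR3B is highest at 3135.

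Cytotoxic T and NK cell genes separated the samples in another way. NKG7 ranged from 2054 in NOR 1 to 7464 in NOR 4 (SD 0.76), GNLY, which encodes the lytic protein granulysin, from 1505 in NOR 1 to 12673 in NOR 5 (SD 1.20), PRF1, the perforin gene, from 974 to 3786 (SD 0.96), and GZMH, a granzyme gene, from 228 to 1889 (SD 1.37). GZMK, a granzyme gene with another course, ranged from 531 to 1502 (SD 0.51, or 0.33 without NOR 3). The median SD of the 10 measured genes was 0.86 against 0.30 for random lists (adjusted p = 0.0014), and their mean r was 0.72 (adjusted p = 0.000525). Adjusted over the list alone 7 genes passed the variance test, and over all genes tested 0 did. The score was between 0.60 and 0.74 in NOR 4, NOR 5 and NOR 6 and between -0.84 and -0.45 in NOR 1, NOR 2 and NOR 3, a 3.00-fold range. The array sets differed by 0.37 (exact permutation p = 0.8), and the block gave a mean r of 0.78 (adjusted p = 0.000525).

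Platelet genes had the highest mean r of the 21 lists, 0.79 (11 genes, adjusted p = 0.000525). The chemokine genes PPBP and PF4 had SD values of 0.37 and 0.42 (PF4 0.24 without NOR 6), and GP9, part of the platelet von Willebrand factor receptor, ranged from 511 to 1692 (SD 0.77, or 0.48 with the block). MYL9, a myosin light chain gene, ranged from 108 in NOR 5 to 794 in NOR 3 (SD 1.20). The median SD was 0.74 against 0.30 for random lists (adjusted p = 0.0014). Adjusted over the list alone 5 genes passed the variance test, and 0 over all genes tested. The score ranged 2.71-fold, from -0.70 in NOR 5 to 0.74 in NOR 4. It was 0.70 higher in array set B (exact permutation p = 0.2), and with the block the mean r was 0.80 (adjusted p = 0.000525).

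Monocyte genes moved together within a narrower range, 1.48-fold between the highest and lowest score. CD14 ranged from 4473 in NOR 5 to 10981 in NOR 3 (SD 0.48, or 0.25 with the block and 0.31 under quantile normalization), LYZ, which encodes lysozyme, from 2061 in NOR 5 to 10951 in NOR 3 (SD 0.84, or 0.46 without NOR 5), and S100A9, a calprotectin subunit, from 6913 to 18667 (SD 0.60, or 0.23 with the block). FCER1G had the smallest SD, 0.20 (0.12 with the block). The 20 measured genes had a mean r of 0.32 (adjusted p = 0.0077) and a median SD of 0.43 against 0.31 for random lists (adjusted p = 0.0199). Adjusted over the list alone 0 genes passed. The score was 0.37 in NOR 3 and 0.35 in NOR 6 and between -0.20 and -0.16 in the others, 0.35 higher in array set B (exact permutation p = 0.4). The mean r was 0.33 with the block (adjusted p = 0.0072) and did not pass without NOR 3 (0.26, adjusted p = 0.0678), with no scaling (0.34, adjusted p = 0.0638) or with no filter (0.23, adjusted p = 0.0513). The call on the SD ended under quantile normalization (0.38, adjusted p = 0.0658).

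Erythroid genes also moved together, with a mean r of 0.58 over 5 measured genes (adjusted p = 0.00945). NOR 3 had the highest score, 1.32, and without it the list had too few measured genes for a test. ALAS2, the first enzyme of heme synthesis in red cell precursors, stood at 2150 in NOR 3 and between 114 and 293 in the other 5 samples (SD 1.55, or 0.50 without NOR 3). BLVRB, a heme breakdown enzyme of red cells, ranged from 558 to 1877 (SD 0.66, or 0.43 without NOR 3 and 0.41 with the block). Their median SD of 0.68 did not pass (adjusted p = 0.132), and adjusted over the list alone 1 gene passed. The score was 0.88 higher in array set B (exact permutation p = 0.1). The mean r did not pass with the block (0.40, adjusted p = 0.0661), with no scaling (0.49, adjusted p = 0.0742) or with the first principal component removed (0.30, adjusted p = 0.0989). The SD passed under 3 of 14 alternatives.

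T cell, B cell and dendritic cell genes passed neither list test. CD3D ranged from 1320 to 2289 (SD 0.31), CD3E from 1823 to 4125 (SD 0.41) and GATA3, a transcription factor, from 321 to 406 (SD 0.12, while a second probe set had 0.465 and r = -0.71 with it). The T cell list (12 genes) had a mean r of 0.17 (adjusted p = 0.262, and 0.09 without NOR 4) and a median SD of 0.34 (adjusted p = 0.483), and the B cell list (8 genes) -0.08 (adjusted p = 0.814) and 0.37 (adjusted p = 0.668). The T cell list passed on its SD with the block (0.35, adjusted p = 0.0492) and on its mean r under quantile normalization (0.17, adjusted p = 0.0434). MS4A1, the CD20 gene, ranged from 334 to 642 (SD 0.39). Dendritic cell genes (6) had a mean r of 0.17 (adjusted p = 0.183, and -0.05 without NOR 6) and a median SD of 0.37 (adjusted p = 0.614), with FCER1A between 785 and 1651. In each of these 3 lists 0 genes passed when adjusted over the list alone. Plasma cell and immunoglobulin genes were too few for a test (4), with IGHM between 2183 and 5341 (SD 0.57, or 0.17 with the block and 0.38 over the mean of its probe sets). PECAM1 (711 to 1104) was the 1 endothelial gene past the filter, and APOC3 (152 to 208) the 1 gene past it of 15 hepatocyte genes with values, a list not expected in blood.

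**Figure D2:**
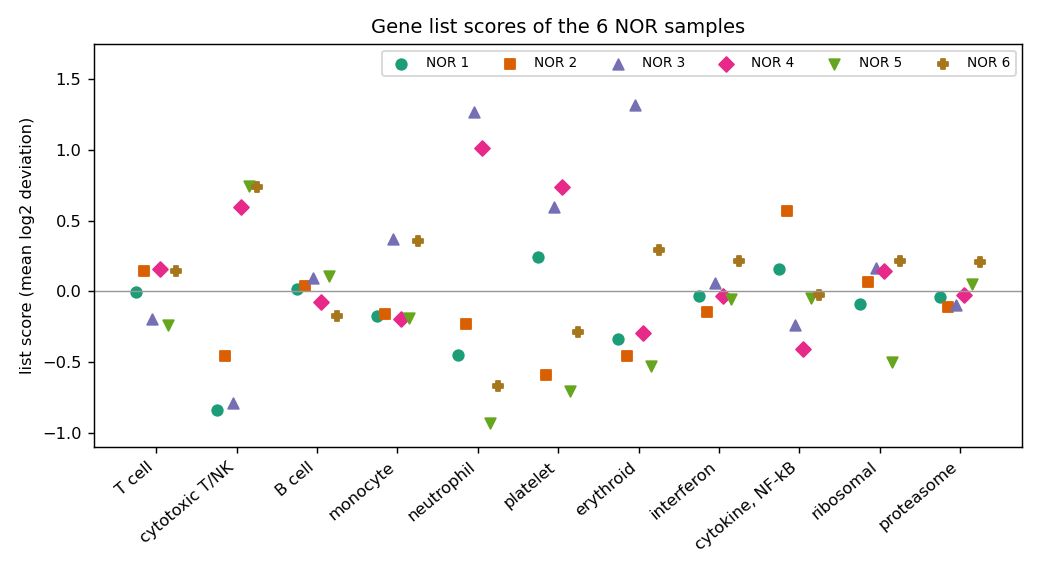
List scores (mean log2 deviation of a list's genes from their own means over the samples) of 11 gene lists in the 6 NOR samples, 1 point per sample. The neutrophil score is highest in NOR 3 (1.27) and NOR 4 (1.02), the cytotoxic score in NOR 4, NOR 5 and NOR 6 (0.60 to 0.74) and the erythroid score in NOR 3 (1.32).

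Among response lists, the inflammatory cytokine and NF-kB list had a mean r of 0.24 over 14 genes (adjusted p = 0.00945). IL1B ranged from 139 in NOR 4 to 1035 in NOR 2 (SD 1.06), the chemokine genes CXCL8 from 117 to 658 (SD 1.18) and CCL4 from 218 to 2041 (SD 1.29), and PTGS2, the inducible cyclooxygenase, from 123 to 706 (SD 0.99, or 0.47 with the block). Adjusted over the list alone 4 genes passed the variance test. The list's median SD was 0.42 (adjusted p = 0.158), and it passed under 8 of 17 alternatives, among them the block (0.42, adjusted p = 0.021). The mean r did not pass without NOR 2 (0.10, adjusted p = 0.174) or with no scaling (0.33, adjusted p = 0.0638), and with the block it was 0.29 (adjusted p = 0.0032). The immediate early list holds transcription factors and other genes induced soon after a stimulus. It had a mean r of 0.21 over 15 genes (adjusted p = 0.0469) and a median SD of 0.43 (adjusted p = 0.0518). FOS ranged from 697 in NOR 6 to 2822 in NOR 2 (SD 0.71) and JUNB from 636 to 1892 (SD 0.59), while IER2 had an SD of 0.13 (0.08 without NOR 6), and adjusted over the list alone 0 genes passed. The mean r passed under 9 of 18 alternatives. It did not with the block (0.20, adjusted p = 0.088), without NOR 2 (0.05, adjusted p = 0.417), NOR 3 (0.23) or NOR 4 (0.22), with the lower floor (0.10), no scaling (0.29), no filter (0.05), Spearman (0.19) or the first principal component removed (0.24), while the SD passed under 9 of 17, among them the block (0.44, adjusted p = 0.00315).

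Genes of 2 large complexes moved together by small amounts, with 0 genes of either past the variance test when adjusted over the list alone. The 38 cytosolic ribosomal protein genes had a mean r of 0.73 (adjusted p = 0.000525) at a median SD of 0.31 (adjusted p = 0.483), with the score at -0.50 in NOR 5 and between -0.09 and 0.22 in the others. The ribosomal score was 0.35 higher in array set B (exact permutation p = 0.1, the smallest possible). RPS25 ranged from 7392 to 16511 and RPL6 from 6623 to 8241. The mean r fell to 0.29 without NOR 5 (adjusted p = 0.027) and to 0.04 under quantile normalization (adjusted p = 0.0622), and it was 0.73 with the block (adjusted p = 0.000525). The 30 proteasome genes had a mean r of 0.17 (adjusted p = 0.0077), a median SD of 0.24 (adjusted p = 0.0518) and an SD of 0.12 for PSMB9 (0.24 with no scaling). Their mean r did not pass without NOR 6 (0.03, adjusted p = 0.308) or with Spearman (0.11, adjusted p = 0.0672), and with the block it was 0.25 (adjusted p = 0.0025). Their SD passed, below random lists, under 3 of 17 alternatives.

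The other 9 lists passed neither test, and adjusted over the list alone 1 glucocorticoid response gene passed the variance test and 0 genes of the other 8 did. Type I interferon response genes (23) had a mean r of 0.09 (adjusted p = 0.0892), with MX1 between 631 and 1103 (SD 0.29). That mean r passed under 4 of 18 alternatives: without NOR 1 (0.13, adjusted p = 0.0362) or NOR 3 (0.14, adjusted p = 0.0371), with the higher floor (0.19, adjusted p = 0.0346) and with the first principal component removed (0.14, adjusted p = 0.0407). Without NOR 6 it was -0.02 (adjusted p = 0.728). The BMP list passed without NOR 2 (0.22, adjusted p = 0.0491), and the SD of the oxidative phosphorylation list, below random lists, under 3 of 17. The BMP score was 0.36 higher in array set B (exact permutation p = 0.1, the smallest possible), and the block lowered the list's mean r to 0.025. Scores of the interferon list (0.16 higher in set B) and the oxidative phosphorylation list (0.12 higher) had the same exact permutation p of 0.1. The mean r was 0.15 for proliferation genes (8), 0.14 for BMP, endothelin, nitric oxide and prostacyclin signalling (9), pathways that drugs for pulmonary hypertension target, 0.06 for hypoxia genes (14), 0.00 for heat shock genes (9), -0.05 for glucocorticoid response genes (5), 0.37 for MHC class II genes (7), 0.16 for reference genes (9) and 0.08 for oxidative phosphorylation genes (30), with adjusted p between 0.136 and 0.723. Several of these rest on 1 sample: the MHC class II value was 0.12 and the reference value 0.01 without NOR 6, the proliferation value 0.02 and the oxidative phosphorylation value 0.03 without NOR 5, and the BMP value 0.06 and the hypoxia value 0.01 without NOR 4. The BMP list had values for 33 genes, of which 9 passed the filter. BMPR2, ACVRL1, BMPR1A and ID1 were not among these 9, so the list result does not cover them. Of its measured genes, NPR1, a natriuretic peptide receptor gene, ranged from the floor in NOR 2 to 462 in NOR 4 (SD 0.98, or 0.64 without NOR 4). TGFBR2 ranged from 1068 to 2054 (SD 0.38). FKBP5, induced by glucocorticoids, ranged from 263 to 1201 (SD 0.88). COX6C had an SD of 0.11 (2172 to 2618, and 0.18 with no scaling) and HLA-DRA of 0.16 (11325 to 15045), while SD values of the reference genes were 0.60 for GAPDH (0.15 with the block), 0.69 for HPRT1 (0.34 without NOR 3), 0.33 for ACTB (0.13 with the block), 0.29 for B2M (0.15 without NOR 5) and 0.24 for YWHAZ.

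**Figure D3:**
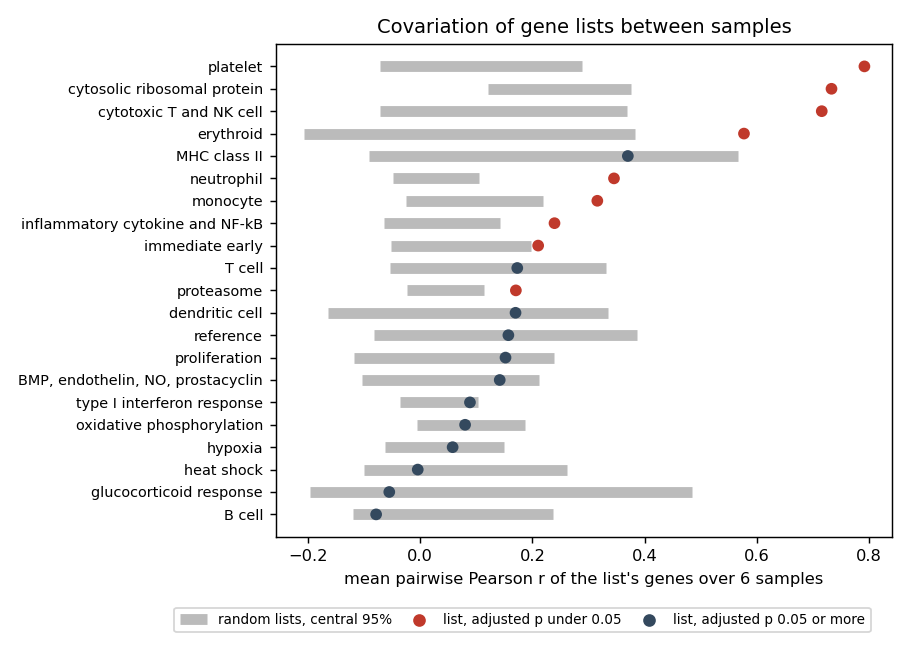
Mean pairwise Pearson r of each list's genes over the 6 NOR samples (points) for 21 gene lists, with the central range of 10000 random matched lists (bars). The 9 lists with an adjusted p under 0.05 lie between 0.17 (proteasome) and 0.79 (platelet).

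In all, 9 of 21 lists passed the covariation test and 4 the test of SD, all 4 with a higher SD than random lists. Of the 3 genes past the variance threshold, 2 belonged to the neutrophil list (Fisher's exact test, adjusted p = 0.0041), the 1 list enriched. Fisher's exact test takes genes as independent, while LTF and CAMP moved together, so its p-value overstates the evidence. Neither LTF nor CAMP passed with the array set as a block.

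Whether cell types moved with or against each other was asked of 21 pairs of list scores, and 0 passed after correction. An unadjusted exact permutation p under 0.05 was reached by 2 pairs. Monocyte and erythroid scores had r = 0.89 (exact permutation p = 0.0222, adjusted p = 0.467, rho = 0.60, exact p = 0.242). The relation rests on NOR 3 and NOR 6, whose monocyte scores were 0.37 and 0.35. Without these 2, the farthest from the median, r was -0.22. The remaining monocyte scores lay between -0.20 and -0.16, too narrow a range for that r to decide anything. Neutrophil and platelet scores had r = 0.84 (exact permutation p = 0.0458, adjusted p = 0.481, rho = 0.77, exact p = 0.103), and 0.29 without the 2 farthest samples. With the array set as a block and exact permutation within sets, the values were 0.79 (p = 0.417) and 0.74 (p = 0.167), and 3 samples per set are too few for a value within each. Of 21 list scores, 0 had a sample past Dixon's value.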

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

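The tests on neutrophil genes, cytotoxic genes, array sets, RNA degradation and other splits of the arrays were chosen only after the results were seen. The test of cell type genes between the sets was not, though the sets themselves were found after the values were seen.

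A sample far from the other 5 was found for 4 of the 119 named genes, where chance at about 1 in 20 gives 6.0. ALAS2 stood at 2150 in NOR 3 against 293 in the next sample (Dixon's ratio 0.6775). MX2, an interferon-induced gene, stood at 669 in NOR 3 against 500 (0.6456). IRF8, a transcription factor of dendritic cells and monocytes, stood at 417 in NOR 1 against 627 (0.677), and TSC22D3, induced by glucocorticoids, at 2290 in NOR 1 against 3193 (0.6539).

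Neutrophil genes varied together between samples. The score of 11 granule protein genes of immature neutrophils was picked after their values were seen. In array set B it was 2.23 in NOR 3, 1.62 in NOR 4 and -0.55 in NOR 6. In set A it was -0.58 in NOR 2, -1.24 in NOR 1 and -1.48 in NOR 5. The sets thus did not overlap, by a narrow margin. An equal shift between the array sets as the whole cause is argued against. With the set as a block the planned list of 18 genes had a mean r of 0.558, above the 0.110 that bounds random lists. A set effect that differs in size between arrays is not removed by the block and stays open. The first principal component ran from 18.3 in NOR 3 to 12.7 in NOR 4 and 3.19 in NOR 6, the order of the granule score. The component was computed from the tested genes, the granule genes among them, so this order is partly built in and is no separate evidence. The mean r of the planned list still passed with the first principal component removed. A changing share of mature neutrophils was predicted to raise the score of 7 genes of mature cells with the granule score. These genes were picked after their values were seen too. The 2 scores had r = -0.23 (exact permutation p = 0.63, rho = -0.43, exact p = 0.419, r = -0.42 without the 2 farthest samples). That sign is opposite, but the samples are too few to decide. The prediction also holds only if mature cells carry the granule transcripts, which were listed as those of immature neutrophils. The test therefore cannot tell whether a share of mature cells plays a part. Members of the mature score differed: r with the granule score was above 0 for 4 genes and below 0 for 3. It was -0.73 for FCGR3B and CXCR1 and 0.80 for MMP9, none of them tested. The design gives no group by which to test a biological explanation.

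With the array set as a block the cytotoxic T and NK cell genes kept a mean r of 0.782. This lies above the 0.377 that bounds random lists, which argues against an equal shift between the sets as the whole cause. A set effect that differs in size between arrays is not removed by the block. Dilution of all lymphocytes by other cells as the whole cause is argued against too. The T cell score would then follow the cytotoxic score with a slope near 1, and the slope was 0.0387 (SE 0.114). The SD values of the 2 scores, 0.18 for T cell and 0.77 for cytotoxic genes, had already kept that slope well below 1. Dilution as a part of the cause stays open. A different share or state of cytotoxic cells between samples may remain and was not tested, since the design gives no group for it.

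Between the array sets, 59 genes differed in limma (adjusted p under 0.05), 27 higher in set B and 32 lower. FCGR3B (-2.22 on the log2 scale, set B minus A), PTGS2 (-1.64), S100A9 (1.03) and the reference gene GAPDH (1.06) were among them. The 10 splits of 6 arrays into 3 and 3 are too few for a share under 0.05. Of them 1, the real one, gave 59 genes and the highest other gave 5. At an unadjusted limma p under 0.05 the real split gave 513 genes and the others 26 to 119. The 3' to 5' ratios of 2 control transcripts lay between 0.837 and 1.36 for GAPDH and between 0.759 and 1.30 for beta-actin. Neither had a large 3' excess on any array, which argues against strong RNA degradation for these 2. A smaller difference in degradation could contribute and stays open, because 0 of 2 ratios separated the sets, which neither requires nor excludes it. A different cell mix stays open as well: 5 of the 59 genes came from the cell type lists against 2.62 at random (96 genes, Fisher's exact p = 0.184).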

How the results depend on the processing

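The array-set block, the filled-in probe sets in the percentiles and enrichment at an unadjusted p were chosen only after the results were seen; the others were planned. No paired analysis was possible because the labels give only 1 group. The cytotoxic and platelet lists kept both calls under every alternative run, with mean r from 0.58 to 0.78 and from 0.54 to 0.87. The count of variable genes, 3, became 0 under quantile normalization, with no scaling, with no filter, with filled-in probe sets counted, without the robust prior and without the trend, 5 with the stricter filter, 1 with the array set as a block, and 0 to 15 with 1 sample left out. Without NOR 4, NOR 5 or NOR 6 it was 0, without NOR 1, 15 and without NOR 2, 5. The count of covarying lists, 9, became 4 with no scaling (platelet, ribosomal, cytotoxic and proteasome). The count of lists with another SD than random lists, 4, became 7 with the block, which added the T cell, immediate early and cytokine lists, and 4 to 8 with 1 sample left out (7 without NOR 3, 8 without NOR 6). The count of enriched lists, 1, became 0 with the lower floor, quantile normalization, no scaling, no filter, filled-in probe sets and the block, 4 at an unadjusted p, and 0 to 1 with 1 sample left out (0 without NOR 4, NOR 5 or NOR 6). Where 0 genes were called, a list's share of them has no value. Scores with an outlying sample, 0, became 2 with the lower floor, 2 with median scaling, 1 with no scaling, 1 with no filter and 2 with filled-in probe sets. Array agreement was 0.966 over all probe sets. Some values lay on the other side of random expectation from the main value, which had passed its test only for the neutrophil list. The median SD of ribosomal genes, 0.31 against 0.29 for random lists (adjusted p = 0.483), lay below random lists under quantile normalization (0.146, adjusted p = 0.00105) and without NOR 5 (0.202, adjusted p = 0.0109), within 0.202 to 0.340 over the samples left out. The neutrophil list held 0 of the 1 gene called with the block. At an unadjusted p the cytotoxic list held 7, the platelet list 6 and the cytokine list 6, where each had held 0. The looser threshold calls more genes by construction; otherwise the cause was not tested. Signal over background limits the 40% of intensities at the floor.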

Other observations

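The test of MYOM2 was chosen only after the result was seen, and the test of cytokine genes before, though with a list of mature neutrophil genes written after the values were seen.

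Several genes outside the naming rule, chosen after their values were seen, stood next in the variance test without passing it. DEFA4, a defensin gene, and ELANE, the neutrophil elastase gene, had SD values of 1.98 and 2.02 and an adjusted limma p of 0.0557. SORL1, a sorting receptor gene, had an SD of 1.43 (adjusted p = 0.087), and its level in array set B fell by 2.41 on the log2 scale from that in set A (adjusted p = 0.0168 in limma). At an unadjusted p under 0.05, a set chosen after the values were seen, genes were enriched in 4 lists: 14 of 18 neutrophil genes (adjusted Fisher's exact p = 2.91e-13), 7 of 10 cytotoxic genes (3.06e-06), 6 of 11 platelet genes (0.000121) and 6 of 14 cytokine genes (0.000504). Fisher's exact test takes genes as independent, and the genes of these lists moved together, so these p-values overstate the evidence.

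A hypothesis is that MYOM2 signal comes from cytotoxic lymphocytes, so that its level may follow their score. The correlation was r = 0.54 (exact permutation p = 0.281, adjusted p = 0.63 over 3 such relations, rho = 0.37, exact p = 0.497, r = 0.52 without the 2 farthest samples), which leaves the hypothesis open: NOR 5 stood at 3326, NOR 6 at the floor, and both had cytotoxic scores of 0.74.

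Inflammatory cytokine genes might come from mature neutrophils in the sample. Their scores had r = 0.38 (exact permutation p = 0.461, adjusted p = 0.63, rho = 0.43, exact p = 0.419, r = 0.71 without the 2 farthest samples), which does not decide it with 6 samples.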
